A study of Homo sapiens with 3 samples.

How the data were processed

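Total RNA of T3M-1 Cl-10 cells, sorted for EGFP 2 days after infection with the mock, ELF4 or ELF4(L211M) retrovirus, was labelled with Cy3 and hybridised to human Agilent 8×60K expression arrays, per the labels' protocols. The 3 deposited records each hold 3 array files, which gave 3 groups of 3 arrays. The intensity values (processed green signal) had been background-subtracted and detrended by the scanner software before they were deposited, per the file headers, which name Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.5.3. Coordinates are those of the file headers' build, hg19. The authors also deposited processed log2 values, in 1 column per group, whose medians were 0.01125, 0 and 0 for mock, ELF4 and ELF4(L211M). Differences between these columns matched those between the first arrays of the groups (r = 1, slope 1), so their log2 scale and direction are settled, while the value on which each probe was centred is unknown. They served as an alternative without a test.

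Of 62976 spots per array, 4259 were controls and were left out, as were spots with an outlier flag, and 50599 probes remained after averaging spots. The log2 intensity minus the array's 75th percentile was analysed. A probe was kept where it was well above background on all arrays of at least 1 group (25627 probes), and the probe with the highest mean stood for a gene (19334 genes, 4597 of them with several probes). Probes were named by RefSeq accession (28174), symbol (2618) or synonym (620) through a gene table of assembly GRCh38.p14, used for names only, and 19187 kept the name in the file. Where a gene was not well above background on any array of a group, the fold is a bound: the brighter group's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own.

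limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) was fitted to all 9 arrays with lmFit and eBayes, without a block, and p-values were adjusted by Benjamini-Hochberg. All tests were two-sided. A gene was called at an adjusted p under 0.05, and changes of at least 2-fold were counted separately. Errors after ± are the standard errors of the fit, with 3 arrays per group. For 24 gene lists limma's camera was run with a preset correlation of 0.01, beside an estimated correlation and fry. With the estimated correlation 0 lists were called in each comparison, against 9, 6 and 10 with the preset. The unadjusted p was under 0.05 for 10328, 4088 and 8602 genes in the 3 comparisons. Simulated data had 200 changed genes in each of the ELF4 and ELF4(L211M) groups, not the same ones. The list of interferon-stimulated genes was also raised with ELF4, by 1 on the log2 scale. A log2 change of 1 was called in 76% of genes for ELF4 against mock, 78% for ELF4(L211M) against mock and 78% for ELF4(L211M) against ELF4. A change of 0.5 was called in 24%, 26% and 33%, and 4, 13 and 17 unchanged genes were called. Far fewer genes were changed there than were called for ELF4 in the data, so these shares may differ in the data.

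The lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule named ELF4, per comparison the 8 highest and 8 lowest called genes changed at least 2-fold, without overlap between arrays and above background throughout, up to 3 bound genes per side, and up to 4 called members per list (otherwise 2 with the highest signal). The text gives a part of these members, and lists without a called member in ELF4(L211M) against mock as counts.

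The arrays lay on 2 slides, each scanned once. Array 1 of each group was on slide 1 and arrays 2 and 3 on slide 2, so slide 1 gave medians without a test, and a scan date could not be told apart from the slide. Each group had its own slide column. Deviations from the group means correlated at r = 0.19 to 0.59 between arrays of the same number and at -0.49 to 0.21 between other numbers. Every pair of the same number thus correlated above 0, and the numbers were taken to pair the arrays, from the data and not the labels, although for arrays 2 and 3, which share slide 2, the ranges overlap. Alternatives were quantile normalization, normexp background correction (offset 50), median centring, other filters, a floor, other ways to join probes, a trended and robust variance, fits of 2 groups, blocks for array number and slide, Student's test without moderation, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.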

Results

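Gene expression was measured in T3M-1 Cl-10, a human squamous cell carcinoma line, after infection with a retrovirus that also made the cells express the green fluorescent protein EGFP. The virus carried no insert (mock), the coding information for ELF4, an ETS-family transcription factor, or that for ELF4(L211M), a variant with a single amino acid substitution. EGFP-positive cells were sorted and RNA was taken 2 days after infection. Each of the 3 groups was represented by 3 one-colour arrays, giving 9 arrays in all. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so all p-values measure the spread between arrays, which may be technical, and the number of arrays limits the precision. Between 49.8% and 64.2% of the non-control probes were well above background per array, no spot was saturated, and 19334 genes were tested. Arrays of a group correlated with each other at r = 0.987 to 0.994 across genes. Arrays of different groups did so at 0.947 to 0.991, so the ranges overlapped. Mock array 1, for example, was closer to ELF4(L211M) array 1 on its slide (0.9905) than to mock array 2 (0.9889). The first principal component, with 64.1% of the variance, separated the 3 groups. The second, with 14.0%, separated the 2 slides, each of which held arrays of all 3 groups. The main fit had no block, so the difference between the slides is part of the spread that its p-values measure.

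The expressed gene was examined first. The array carried 1 probe for ELF4 (NM_001421), on chromosome X from 129198905 to 129198964 (hg19), at position 4108 of the transcript, which places it in the 3′ untranslated region and outside the coding sequence. It therefore checks neither the virus insert nor the labels. Its signal differed by -0.35 ± 0.10 (log2, SE) between the ELF4 and mock arrays (adjusted p = 0.0178, lower on 3 of 3 ELF4 arrays), by -0.09 ± 0.10 between ELF4(L211M) and mock (adjusted p = 0.649), and by 0.26 ± 0.10 between ELF4(L211M) and ELF4 (adjusted p = 0.0734). The last passed the threshold with the slide as a block (adjusted p = 0.0158) or the array number as a block (adjusted p = 0.00956), and within slide 2 it did not (adjusted p = 0.131). The lower signal with ELF4 lost its call without mock array 1 (adjusted p = 0.0582), ELF4 array 2 (adjusted p = 0.0605) or ELF4 array 3 (adjusted p = 0.0636), and the variant's difference from ELF4 gained one without ELF4(L211M) array 3 (adjusted p = 0.0349). Within slide 1 the 3 differences were -0.33, -0.05 and 0.28, without a test.

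The comparison of ELF4 with the mock virus asked which genes respond to this protein. LMO2, a transcriptional adaptor known from blood cell development, rose 172-fold (log2 difference 7.42 ± 0.18, SE, n = 3 arrays per group, adjusted p = 6.11e-07). Every one of the 37 measured interferon-stimulated genes rose, by a median of 6.85-fold, among them the antiviral genes CMPK2 (35.1-fold), IFIT2 (30.7-fold) and MX2 (51.8-fold, with a second probe at 0.56 on the log2 scale and not called). Among pro-apoptotic and stress genes HRK (25.4-fold), BBC3 (10.3-fold), GDF15 (10.4-fold) and DDIT3 (9.40-fold) rose. Among genes of DNA replication, mitosis and ribosome biogenesis E2F1 (1.70-fold lower), BUB1B (1.71-fold lower) and ODC1, the first enzyme of polyamine synthesis (2.91-fold lower), fell.

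In all, 9356 of 19334 genes (48.4%) differed between ELF4 and mock in limma's moderated test at an adjusted p under 0.05, 4430 higher and 4926 lower. Of the 2864 that also changed at least 2-fold, 1727 were higher and 1137 lower. By detection, 217 genes were well above background on all ELF4 arrays and on 0 of 3 mock arrays, and 212 of them were called. The reverse held for 66 genes, of which 59 were called. Genes selected in this way are likely to be called, so these calls add no independent support. With the slide as a block 10700 genes were called, and within slide 2 alone 8433. With another background correction (normexp, followed by quantile normalization) 1491 genes passed the 2-fold limit.

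Among genes above background on all arrays of both groups and without overlap between arrays, the highest besides LMO2, MX2, CMPK2 and IFIT2 were LGALS9C (5.85 ± 0.17, adjusted p = 8.64e-07), FAM83E (4.88 ± 0.23), STAC3 (4.79 ± 0.29) and the small GTPase gene RASL10A (4.73 ± 0.32). LGALS9C has near-identical paralogs, so its probe may not tell them apart. CXCR2, a receptor for the CXCL8 group of chemokines, was not well above background on any mock array and was at least 26.3-fold higher with ELF4 (adjusted p = 4.3e-06), FAM153B at least 16.1-fold and the phospholipid scramblase gene PLSCR4 at least 15.9-fold. The lowest values among the genes so limited were those of PAQR5 (-2.45 ± 0.13, adjusted p = 5.34e-06), the T-box factor gene TBX1 (-2.42 ± 0.10), FAM161A (-2.38 ± 0.18), FAM27E3 (-2.36 ± 0.37), the transmembrane protein gene HEG1 (-2.26 ± 0.11), CYP1A1, an enzyme of xenobiotic metabolism (-2.25 ± 0.30), MVB12B (-2.24 ± 0.16) and TMEM158 (-2.23 ± 0.20). Signals of the cytokine receptor gene IL20RA, the connexin gene GJB6 and TARS3 were not well above background on the ELF4 arrays and were at least 3.51-fold, 3.37-fold and 3.19-fold lower. On hg19 the LMO2 probe (NM_005574) lies on chromosome 11 from 33880243 to 33880302, the MX2 probe (NM_002463) on chromosome 21 from 42780501 to 42780560, the CXCR2 probe (NM_001557) on chromosome 2 from 219001875 to 219001934 and the HEG1 probe (NM_020733) on chromosome 3 from 124684823 to 124684882.

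**Figure D1:**
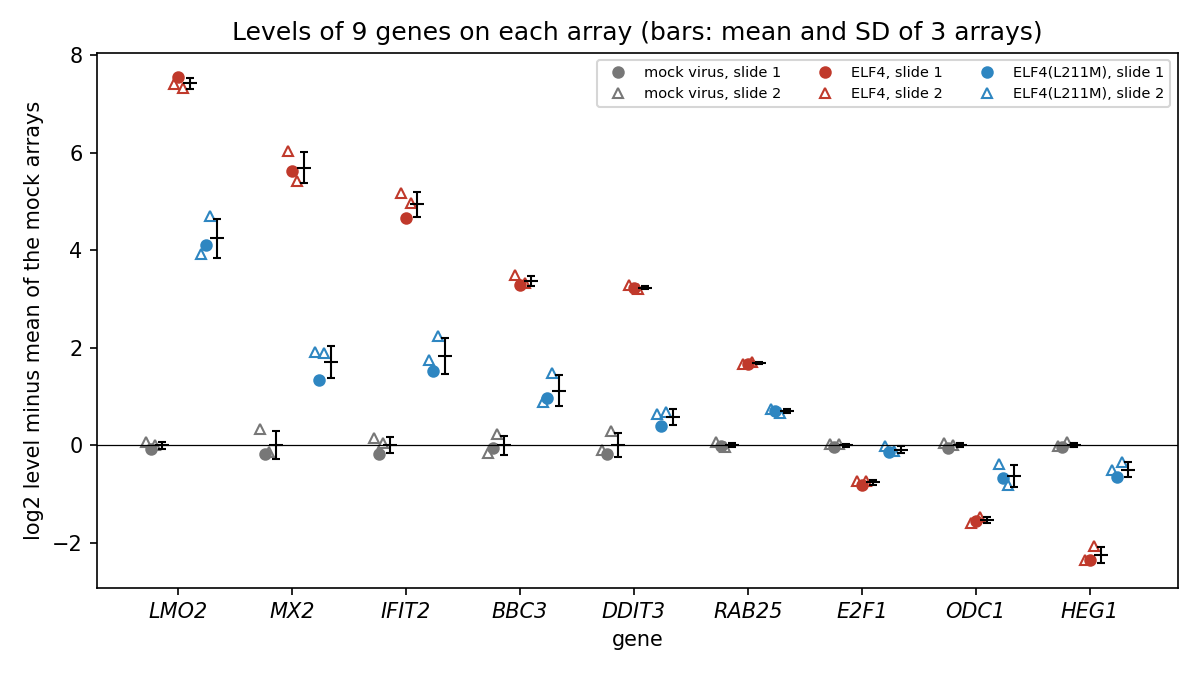
Level of 9 genes on each of the 9 arrays, as log2 signal minus the mean of the mock arrays. Circles are slide 1, triangles slide 2, and the bars give the mean and SD of the 3 arrays of a group. LMO2 had a mean of 7.42 with ELF4 and 4.24 with ELF4(L211M), and HEG1 means of -2.26 and -0.51.

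The interferon-stimulated list rose as a whole (median 2.78, camera adjusted p = 8.48e-20), with 37 of 37 members higher. Camera's call rests on the preset correlation between genes (adjusted p = 0.266 with an estimated correlation). Fry, which does not set the members against other genes, called the list too (fry adjusted p = 1.71e-05). The list's median was 2.74 within slide 1 and 2.71 within slide 2. CXCL10, an interferon-induced chemokine, was higher by 4.94 ± 0.76 and was above background on 1 of 3 mock arrays. RSAD2 was likewise above background on 1 of 3 mock arrays, so its 4.94 ± 1.45 (adjusted p = 0.0220) had a wide error. The MX2 probe named above gave 5.69 ± 0.23. The type I interferon gene IFNB1 itself was at least 7.37-fold higher (adjusted p = 9.8e-05) and not above background on any mock array.

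Of the 16 integrated stress response genes 13 rose and 1 fell (median 0.88, adjusted p = 1.44e-05, and adjusted p = 0.266 with an estimated correlation). DDIT3, a transcription factor of that response, rose by 3.23 ± 0.14, ATF3 by 2.45 ± 0.46 and CHAC1, which degrades glutathione, by 2.44 ± 0.15. Of 20 apoptosis regulators 12 rose and 1 fell (median 0.50, adjusted p = 0.000337, and adjusted p = 0.266 with an estimated correlation). The BH3-only genes HRK (4.67 ± 0.28), BBC3 (3.37 ± 0.17) and PMAIP1 (2.16 ± 0.11) and the death ligand gene TNFSF10 (2.03 ± 0.11) led it. Of 23 p53 target genes 11 rose and 3 fell (median 0.29, adjusted p = 0.0119, and adjusted p = 0.511 with an estimated correlation), with GDF15 at 3.37 ± 0.14, SESN2 at 1.89 ± 0.17 and the CDK inhibitor gene CDKN1A at 1.45 ± 0.18. Of 23 epithelial junction genes 12 rose and 3 fell (median 0.28, adjusted p = 0.0111, and adjusted p = 0.265 with an estimated correlation), among them TJP3 (at least 11.7-fold higher), CLDN4 (1.69 ± 0.12), CRB3 (1.68 ± 0.08) and RAB25 (1.68 ± 0.07). The within-slide medians of these 4 lists were 0.87, 0.63, 0.32 and 0.36 on slide 1 and 0.88, 0.51, 0.27 and 0.29 on slide 2.

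The G1/S and DNA replication genes fell in 17 of 23 cases and rose in 0 (median -0.49, adjusted p = 4.87e-05, and adjusted p = 0.465 with an estimated correlation). UNG (-1.09 ± 0.12), CCNE1 (-0.93 ± 0.10), the replication licensing gene CDC6 (-0.86 ± 0.13) and E2F1 (-0.77 ± 0.07) moved most. Of 25 G2/M and mitosis genes 15 fell and 0 rose (median -0.36, adjusted p = 0.00101, and adjusted p = 0.511 with an estimated correlation), including BIRC5 (-0.77 ± 0.10) and the kinesin gene KIF11 (-0.75 ± 0.08). Of 22 ribosome biogenesis and MYC target genes 18 fell and 0 rose (median -0.49, adjusted p = 6.43e-06, and adjusted p = 0.359 with an estimated correlation), with ODC1 at -1.54 ± 0.11, CAD at -1.06 ± 0.12 and WDR12 at -0.93 ± 0.10. On slide 1 the medians of these 3 lists were -0.45, -0.36 and -0.46, and on slide 2 -0.46, -0.37 and -0.50.

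Markers of other cell types were also listed. Of 17 measured leukocyte markers 9 rose and 0 fell (median 0.55, adjusted p = 0.0119, and adjusted p = 0.265 with an estimated correlation), and limma with a trended, robust variance ended the call (adjusted p = 0.0535). ITGAX was at least 3.81-fold higher, CORO1A rose by 1.62 ± 0.10, NKG7, above background on 1 of 3 mock arrays, by 1.48 ± 0.53 and LAPTM5 by 1.25 ± 0.33, while PTPRC, the general leukocyte marker, had 0.29 ± 0.19 (adjusted p = 0.239). PTPRC passed the threshold with the array number as a block (adjusted p = 0.00801) or the slide as a block (adjusted p = 0.0238). Of 3 measured endothelial markers 2 were called higher (adjusted p = 0.280 for the list), ENG, above background on 2 of 3 mock arrays, by 3.59 ± 0.35 and VWF by 0.67 ± 0.14. VWF turned negative with normexp background correction and with its other probe. Of 2 measured fibroblast markers 1 fell, the collagen gene COL1A1 (-0.59 ± 0.13, adjusted p = 0.537 for the list).

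The remaining 13 lists had members on both sides and were not called by camera. Of 22 ETS family members 8 rose and 7 fell (adjusted p = 0.403), with ETV7 at 3.80 ± 0.21, FEV at least 4.94-fold higher, ELF2 at 1.18 ± 0.14 and ETS1 at -1.21 ± 0.08. Of 8 measured genes known as ELF4 targets 2 rose and 2 fell (adjusted p = 0.912): besides IFNB1, KLF4 rose by 2.52 ± 0.29, KLF2, a quiescence factor of lymphocytes, above background on 2 of 3 ELF4 arrays, fell by 2.02 and IL1RN by 0.91, with a second IL1RN probe at 0.10. Among 28 NF-kB and inflammatory genes 13 rose and 7 fell (adjusted p = 0.280), such as CCL2 (2.21 ± 0.54) and IL1B (-1.28 ± 0.14). Of 16 G1 cyclins, CDKs and CDK inhibitors 3 rose and 4 fell (adjusted p = 0.912), CDKN1C by 1.08 ± 0.11 and CDK4 by -0.84 ± 0.10. Of 24 keratinocyte differentiation genes 7 rose and 5 fell (adjusted p = 0.364), with the cornified envelope genes LCE3D at least 2.58-fold higher and SPRR2A at 2.30 ± 0.10. Of 20 basal keratinocyte genes 2 rose and 7 fell (adjusted p = 0.108), SOX2 by -1.03 ± 0.08 and EGFR by -0.80 ± 0.09, and without a filter on dim probes the list was called (adjusted p = 0.00886). That call used camera's preset correlation, and with an estimated correlation the list, with the filter, had an adjusted p of 0.700. Of 11 mesenchymal genes 1 rose and 3 fell (adjusted p = 0.280), VIM by -1.07 ± 0.21 and CDH2 by -0.93 ± 0.08.

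Of 21 cholesterol synthesis genes 5 rose and 8 fell (adjusted p = 0.537), INSIG1 by 1.89 ± 0.13 and DHCR7 by -1.41 ± 0.11. Of 14 endoplasmic reticulum chaperones 5 rose and 3 fell (adjusted p = 0.280), HERPUD1 by 1.41 ± 0.13. Of 15 heat shock genes 2 rose and 3 fell (adjusted p = 0.912), SERPINH1 by 0.97 ± 0.11. Of 17 hypoxia and glycolysis genes 4 rose and 4 fell (adjusted p = 0.912), NDRG1 by 1.30 ± 0.09 and BNIP3 by -1.02 ± 0.13. Of 17 immediate early genes 7 rose and 4 fell (adjusted p = 0.242), ZFP36, an RNA-destabilizing protein gene, by 1.77 ± 0.17. Of 12 reference genes 2 rose and 3 fell (adjusted p = 0.537), B2M by 0.70 ± 0.19 and SDHA by -0.85 ± 0.10. When adjusted over the list alone, 19 G1/S, 16 G2/M and 19 ribosome biogenesis genes were lower, 2 heat shock genes were lower, 5 hypoxia and glycolysis genes were higher and 5 lower, 8 immediate early genes were higher, and the other 18 lists kept the counts given above. The median, mean and camera direction of a list differed in sign for the known ELF4 targets (median -0.28, mean 0.33), the G1 cyclins (-0.05, 0.09), the cholesterol synthesis genes (-0.13, 0.01) and the hypoxia and glycolysis genes (-0.07, -0.11, camera direction up).

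The comparison of ELF4(L211M) with the mock virus asked what the variant does on its own. LMO2 was again the most raised gene, at 18.9-fold (4.24 ± 0.18, n = 3 arrays per group, adjusted p = 8.86e-05). Of 37 interferon-stimulated genes 16 rose, such as IFIT2 (3.57-fold) and OAS1 (3.43-fold), and 21 were not called. Their median was 1.67-fold higher, a shift that camera called with the preset correlation and not with an estimated one (adjusted p = 0.420 with an estimated correlation). The pro-apoptotic genes HRK (2.68-fold) and BBC3 (2.17-fold) and the junction genes RAB25 (1.63-fold) and CRB3 (1.60-fold) rose. ODC1 fell, to 1.55-fold lower. Most calls of single genes in this comparison were fragile. Of its 46 named genes called, 31 lost the call within slide 2, which leaves fewer arrays, 27 without a filter on dim probes and 24 with only the 2 groups. All 46 kept it with the slide or the array number as a block. So did the 36 that remained when signal above background was required on all 9 arrays.

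In limma's moderated test 1061 genes (5.49%) were called, 804 higher and 257 lower, and 184 of them changed at least 2-fold, 180 higher and 4 lower. CLBA1 (at least 1.87-fold lower) and GCNT2 (at least 1.64-fold lower) were among the lower ones. The count depended on the model: 2372 genes were called with the slide as a block (1436 higher and 936 lower), 2747 with the array number as a block (1612 higher and 1135 lower) and 196 within slide 2 alone, where 169 of the 1061 remained. It was 173 without a filter on dim probes and between 359 and 838 when single arrays were left out. It moved by over 1.5 times without mock array 1 (553), 2 (426) or 3 (359), ELF4 array 2 (588) or 3 (608), and ELF4(L211M) array 1 (610) or 3 (465). With the slide as a block 221 genes changed at least 2-fold (202 higher and 19 lower), with the array number as a block 229 (208 higher and 21 lower), and within slide 2 alone 113. Normexp left 64 with quantile normalization and 61 with the 75th percentile, no filter left 98 and a test of each gene without moderated variance left 40.

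After LMO2 the highest values, among genes above background on all arrays of both groups and without overlap between arrays, were those of LGALS9C (2.51 ± 0.17), the AP-1 repressor gene JDP2 (2.34 ± 0.19, adjusted p = 0.000979), C11orf52 (2.32 ± 0.10), RAB11FIP4 (2.15 ± 0.25), SLC66A3 (2.06 ± 0.17), the sperm calcium channel gene CATSPER1 (2.05 ± 0.11) and B3GALT4 (1.98 ± 0.12). GALNT12, ACP3 and PLSCR4 were at least 4.33-fold, 3.27-fold and 3.03-fold higher, with no mock array above background. Of these, all except GALNT12 also passed within slide 2.

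The interferon-stimulated list was called (median 0.74, camera adjusted p = 3.94e-19, and adjusted p = 0.420 with an estimated correlation), with 16 of 37 members higher over all genes and 30 when adjusted over the list alone. Its median was 0.61 on slide 1 and 0.79 on slide 2. IFIT2 rose by 1.83 ± 0.20, OAS1 by 1.78 ± 0.27, MX2 by 1.71 ± 0.23 and IFI44L by 1.46 ± 0.27. MX2's other probe gave -0.07, and within slide 2 only IFIT2 of these 4 genes stayed past the threshold. Of 20 apoptosis regulators 5 rose and 0 fell (7 and 0 adjusted over the list alone), and the list was called (median 0.21, adjusted p = 0.000147, and adjusted p = 0.420 with an estimated correlation), with HRK at 1.42 ± 0.28, BBC3 at 1.12 ± 0.17, PMAIP1 at 0.67 ± 0.11 and TNFSF10 at 0.58 ± 0.11. Of 23 epithelial junction genes 6 rose and 0 fell, 7 adjusted over the list alone (median 0.10, adjusted p = 0.00278, and adjusted p = 0.181 with an estimated correlation), with TJP3 at least 1.71-fold higher, RAB25 at 0.70 ± 0.07 and CLDN4 at 0.55 ± 0.12. Of 23 p53 target genes 3 rose, with 3 higher and 1 lower adjusted over the list alone (median 0.12, adjusted p = 0.0125, and adjusted p = 0.767 with an estimated correlation), led by BBC3 and by GDF15 (0.74 ± 0.14). Without mock array 1 the p53 call was lost (adjusted p = 0.123), as it was without ELF4(L211M) array 2 (adjusted p = 0.0638).

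Of 25 G2/M and mitosis genes 0 were called singly, and the list was (median -0.14, adjusted p = 0.0117, and adjusted p = 0.791 with an estimated correlation). Of 22 ribosome biogenesis and MYC target genes 1 fell, ODC1 (-0.63 ± 0.11), and the list was called (median -0.15, adjusted p = 0.0222, and adjusted p = 0.817 with an estimated correlation). The ribosome biogenesis call was lost with the slide as a block (adjusted p = 0.0512) and within slide 2 (adjusted p = 0.0534), and both calls were lost without mock array 2 (adjusted p = 0.143 for G2/M and 0.130 for ribosome biogenesis) and without ELF4(L211M) array 3 (adjusted p = 0.0611 and 0.182). On slide 1 the medians of the apoptosis, junction, p53, G2/M and ribosome lists were 0.23, 0.06, 0.09, -0.10 and -0.07, and on slide 2 they were 0.19, 0.13, 0.10, -0.18 and -0.18.

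The other 18 lists were not called by camera (adjusted p from 0.218 to 0.928). Among them ETV7 rose by 1.51 ± 0.21 while ETS1 (-0.36 ± 0.08) and SPDEF (-0.58 ± 0.13) fell, with 1 higher and 2 lower of 22 ETS family members (2 and 4 adjusted over the list alone). Of 21 cholesterol synthesis genes 3 rose, INSIG1 by 0.71 ± 0.13 and STARD4, above background on 1 of 3 mock arrays, by 1.66 ± 0.39 among them (5 higher and 3 lower adjusted over the list alone). The lists with 1 called member were NF-kB (CXCL3, -0.65 ± 0.12, of 28), G1 cyclins (CCND3, 0.55 ± 0.08, of 16), keratinocyte differentiation (LCE3D of 24, above background on 1 ELF4(L211M) array), basal keratinocyte (SOX2, -0.37 ± 0.08, of 20) and mesenchymal genes (of 11). No member was called among the known ELF4 targets, G1/S, fibroblast, leukocyte, endothelial, integrated stress response, endoplasmic reticulum chaperone, heat shock, hypoxia, immediate early and reference lists, by limma over all genes. Adjusted over the list alone, 1 stress response gene was higher, and the G1/S list was called by camera without ELF4(L211M) array 2 (adjusted p = 0.0319). That call used the preset correlation, and with an estimated correlation the list had an adjusted p of 0.875 on all arrays. CXCL8, a known ELF4 target, had -0.42 ± 0.29 (adjusted p = 0.471) and passed with the array number as a block (adjusted p = 0.0368) or the slide as a block (adjusted p = 0.0277), and CD68, a macrophage marker, had 0.31 ± 0.12 (adjusted p = 0.188) and passed likewise (adjusted p = 0.0326 and 0.0419). Median and camera direction differed in sign for the keratinocyte differentiation (-0.02) and heat shock lists (-0.003), both with camera direction up.

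The direct comparison of ELF4(L211M) with ELF4 asked which genes differed between cells given these 2 viruses, whose amounts of protein were not measured. CMPK2 and MX2 were 17.4-fold and 15.8-fold lower with the variant, although a second MX2 probe differed by -0.63 and was not called. Of 37 interferon-stimulated genes 36 were lower, by a median of 4.04-fold over the list. HRK was 9.5-fold lower, DDIT3 6.33-fold and GDF15 6.20-fold. Genes that had been lower with ELF4 were higher with the variant, such as HEG1 (3.38-fold), TBX1 (3.12-fold), E2F1 (1.60-fold) and ODC1 (1.88-fold). LMO2 was lower too, with a log2 difference of -3.18 ± 0.18 (n = 3 arrays per group, adjusted p = 3.4e-05).

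Of 19334 genes 6997 (36.2%) differed in limma's moderated test, 3480 higher and 3517 lower with the variant, and 1377 changed at least 2-fold, 399 higher and 978 lower. With the slide as a block 8744 genes were called, and within slide 2 alone 5515. Normexp background correction with quantile normalization left 585 genes past the 2-fold limit, and requiring signal above background on all 9 arrays left 903.

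Other low values, among genes above background on all arrays of both groups and without overlap between arrays, were those of MCEMP1 (-4.07 ± 0.36), RASL10A (-3.81 ± 0.32), the chaperone gene ERP27 (-3.74 ± 0.27), GOLGA6L6, which has near-identical paralogs (-3.72 ± 0.30), FAM83E (-3.58 ± 0.23) and CXCR2 (-3.42 ± 0.31). RSAD2, FBXO15 and LINC00324 were not above background on the ELF4(L211M) arrays and were at least 29.6-fold, 21.5-fold and 13.8-fold lower. Among the genes so limited, the highest values after HEG1 (1.76 ± 0.11, adjusted p = 4.51e-05) were those of the adrenergic receptor gene ADRA2C (1.72 ± 0.43), MTARC1 (1.66 ± 0.12), MIR17HG, host of the miR-17 cluster (1.64 ± 0.19), TBX1 (1.64 ± 0.10), SPIRE2 (1.60 ± 0.16), FAM161A (1.60 ± 0.18) and CEP68 (1.60 ± 0.30). SNORD36B, ALPK2 and GPR153 were at least 2.10-fold, 2.07-fold and 1.81-fold higher.

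Camera called 10 lists. Interferon-stimulated genes were lower (median -2.01, adjusted p = 1.53e-20, and adjusted p = 0.279 with an estimated correlation), by -2.12 on slide 1 and -2.01 on slide 2. So were 13 of 16 integrated stress response genes (median -0.78, adjusted p = 2.76e-07, and adjusted p = 0.227 with an estimated correlation), DDIT3 by -2.66 ± 0.14 and CHAC1 by -2.23 ± 0.15. Among 20 apoptosis regulators 10 were lower and 0 higher (median -0.32, adjusted p = 0.00217, and adjusted p = 0.325 with an estimated correlation), with BBC3 at -2.25 ± 0.17 and PMAIP1 at -1.50 ± 0.11. Of 23 p53 target genes 11 were lower and 2 higher (median -0.20, adjusted p = 0.0293, and adjusted p = 0.497 with an estimated correlation), CDKN1A by -1.05 ± 0.18 and SESN1, above background on 2 of 3 ELF4 arrays, by 1.20 ± 0.16. Of 23 epithelial junction genes 10 were lower and 3 higher (median -0.28, adjusted p = 0.0279, and adjusted p = 0.227 with an estimated correlation), CLDN4 by -1.13 ± 0.12. Of 17 leukocyte markers 7 were lower and 0 higher (median -0.46, adjusted p = 0.00842, and adjusted p = 0.227 with an estimated correlation), ITGAX by at least 3.51-fold and CORO1A by -1.22 ± 0.10.

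Higher with the variant were 17 of 23 G1/S and DNA replication genes (median 0.39, adjusted p = 2.81e-06, and adjusted p = 0.341 with an estimated correlation), UNG by 0.81 ± 0.12 among them, and 7 of 25 G2/M and mitosis genes (median 0.23, adjusted p = 0.00457, and adjusted p = 0.497 with an estimated correlation), with BUB1B at 0.57 ± 0.07. The same held for 17 of 22 ribosome biogenesis and MYC target genes (median 0.40, adjusted p = 7.6e-07, and adjusted p = 0.325 with an estimated correlation), CAD by 0.96 ± 0.12. Of 20 basal keratinocyte genes 5 were higher and 1 lower (median 0.24, adjusted p = 0.0411, and adjusted p = 0.568 with an estimated correlation), SOX2 by 0.67 ± 0.08 and DST by 0.92 ± 0.08, whose other probe gave -0.17. The basal keratinocyte call was lost without ELF4 array 1 (adjusted p = 0.166) and without ELF4(L211M) array 2 (adjusted p = 0.0642) or 3 (adjusted p = 0.137), and the p53 call without ELF4 array 3 (adjusted p = 0.0668) or ELF4(L211M) array 1 (adjusted p = 0.0748). Leaving out ELF4(L211M) array 1 also ended the junction call (adjusted p = 0.0566). On slide 1 the stress response, apoptosis, p53, junction and leukocyte medians were -0.74, -0.35, -0.24, -0.35 and -0.49, and on slide 2 -0.80, -0.28, -0.23, -0.24 and -0.21, while the G1/S, G2/M, ribosome and basal keratinocyte medians were 0.46, 0.26, 0.47 and 0.19, and 0.38, 0.20, 0.36 and 0.25.

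Of the 14 lists not called (camera adjusted p from 0.169 to 0.923), the ETS family had 5 higher and 8 lower of 22, with FEV at least 4.55-fold lower, ETV7 at -2.30 ± 0.21 and ETS1 at 0.85 ± 0.08. The known ELF4 targets had 1 higher, KLF2 (1.17 ± 0.27, above background on 2 of 3 ELF4 arrays), and 2 lower, IFNB1 (-3.05 ± 0.40, above background on 1 of 3 ELF4(L211M) arrays) and KLF4 (-1.65 ± 0.29). Inflammatory genes had 4 higher and 10 lower of 28, G1 cyclins 4 and 3 of 16, keratinocyte differentiation 2 and 6 of 24 (SPRR2A -2.03 ± 0.10), mesenchymal genes 2 and 0 of 11, fibroblast markers 1 and 0 of 2, and endothelial markers 0 and 2 of 3 (ENG -2.94 ± 0.35, above background on 2 of 3 ELF4(L211M) arrays, and VWF, which turned positive with normexp). Cholesterol synthesis genes had 8 higher and 4 lower of 21 (DHCR7 1.06 ± 0.11), chaperones 1 and 3 of 14, heat shock genes 2 and 1 of 15, hypoxia and glycolysis genes 3 and 5 of 17 (NDRG1 -1.38 ± 0.09), immediate early genes 3 and 6 of 17 (ATF3 -2.40 ± 0.46) and reference genes 3 and 1 of 12. Adjusted over the list alone, the counts lower were 9 for the ETS family, 11 for apoptosis, 13 for junction, 14 for stress response, 6 for hypoxia, 7 for immediate early and 2 for reference genes, and the counts higher were 6 for the ETS family, 18 for G1/S, 5 for G2/M, 18 for ribosome biogenesis and 4 for reference genes. Median and mean differed in sign for the known ELF4 targets (0.19 and -0.34) and the reference genes (-0.02 and 0.05).

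**Figure D2:**
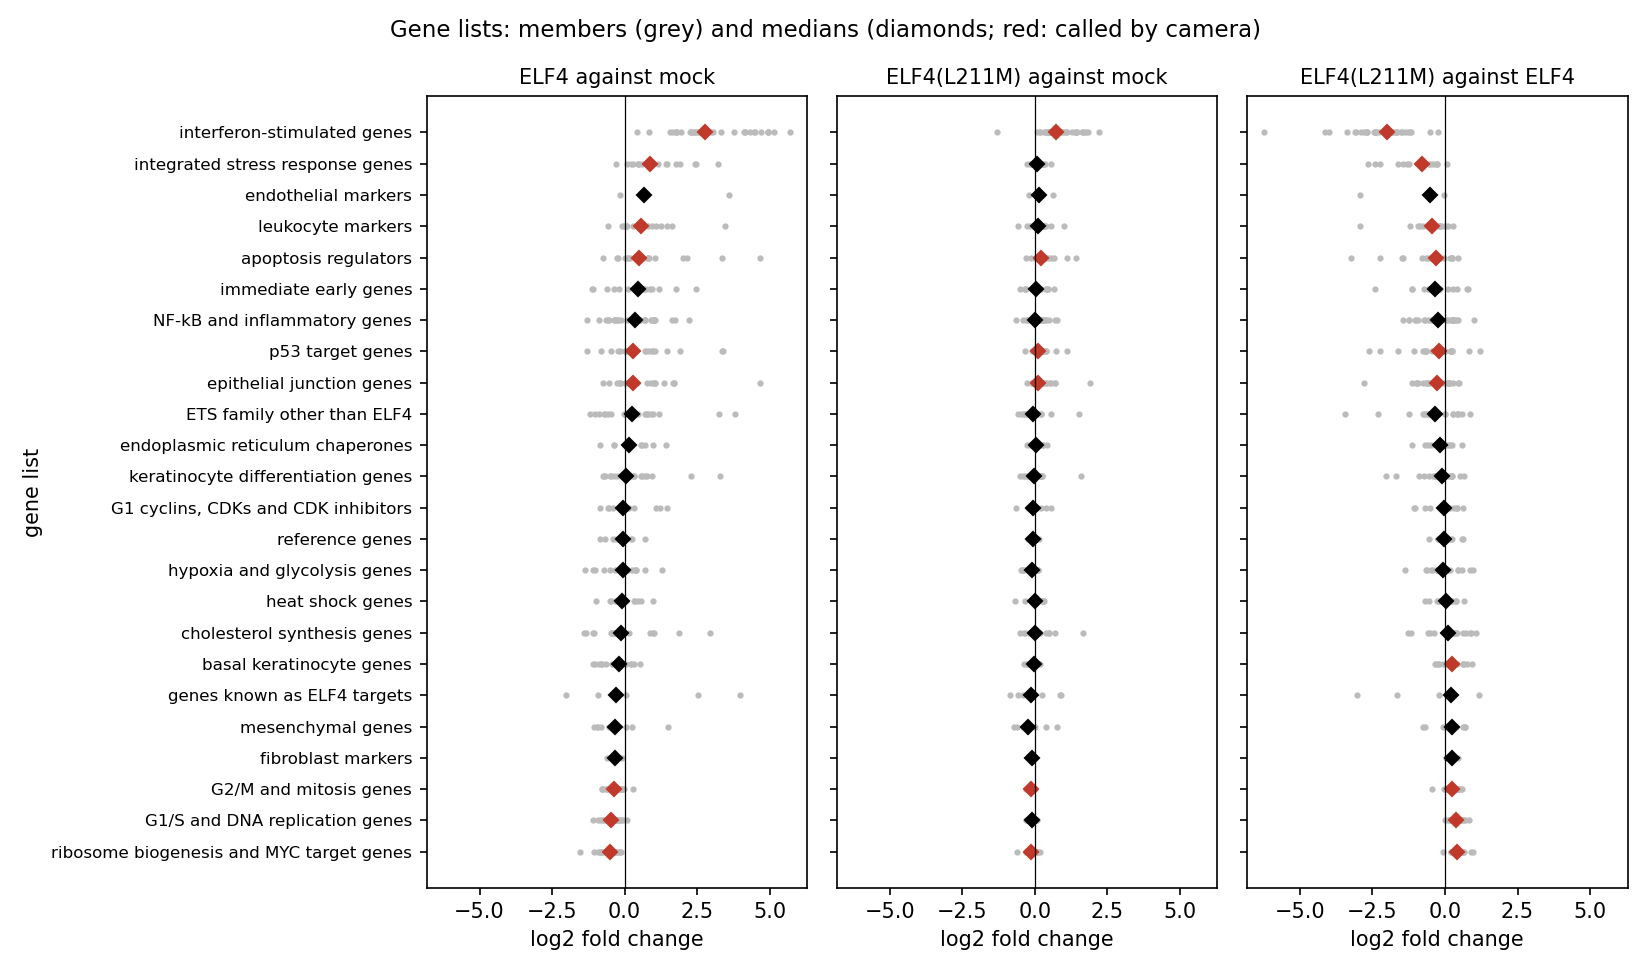
Members (grey dots) and medians (diamonds, red where camera called the list) of the 24 gene lists in the 3 comparisons, as log2 fold change. The interferon-stimulated genes had medians of 2.78, 0.74 and -2.01.

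How far the effects of both proteins resembled each other was measured across genes, which are not independent replicates. The log2 fold changes against mock correlated at r = 0.74, where unchanged groups set against the same mock arrays gave a mean of 0.50 and at most 0.53 in 100 simulated draws. Their covariance was 0.214, against 0.0238 in the simulation, a difference of 0.191 that estimates the shared effect. The slope of the variant's changes on ELF4's was 0.30. The sign was the same in 79.2% of genes, against 66.6% in the simulation. Within slide 1 the correlation was 0.64, within slide 2 it was 0.72, and with the slide as a block 0.74.

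Of the genes called, 798 were higher in both comparisons and 250 lower in both, where independent lists of these sizes would share 184 and 65.5. The 3 mock arrays are too few to give each effect 2 of its own, so part of the excess may come from sharing them. With single arrays of slide 2 and a different mock array for each effect, chosen after seeing the data, the correlation was 0.59 and 0.50 and the covariance 0.264 and 0.181. Of all genes tested, 1 (NTNG2) was called in opposite directions, and its call with the variant was lost within slide 2. A further 12 genes were called with the variant and not with ELF4. Among them OR5V1 had 0.81 with the variant and -0.006 with ELF4, and limma called the difference (adjusted p = 0.0035). For SYNE1 (-0.47 and -0.23) the difference was not called (adjusted p = 0.0813). These 12 genes were chosen by their calls on the same arrays, so a called difference among them adds no independent support. Of the 2864 genes that ELF4 changed at least 2-fold, 2724 (95.1%) had the same sign with the variant, and 809 were called in the same direction. This share, too, rests on shared mock arrays, and with different ones it was 91.2% of 3255 and 86.7% of 3385 genes changed at least 2-fold on the ELF4 array. Called closer to mock with the variant than with ELF4 were 2585 (90.3%), as a variant without any effect would also give, while 0 were called further from it. The variant's log2 change was a median of 0.32 of ELF4's among the genes that rose and 0.30 among those that fell, and 0.29 among the 35 interferon-stimulated genes raised at least 2-fold.

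**Figure D3:**
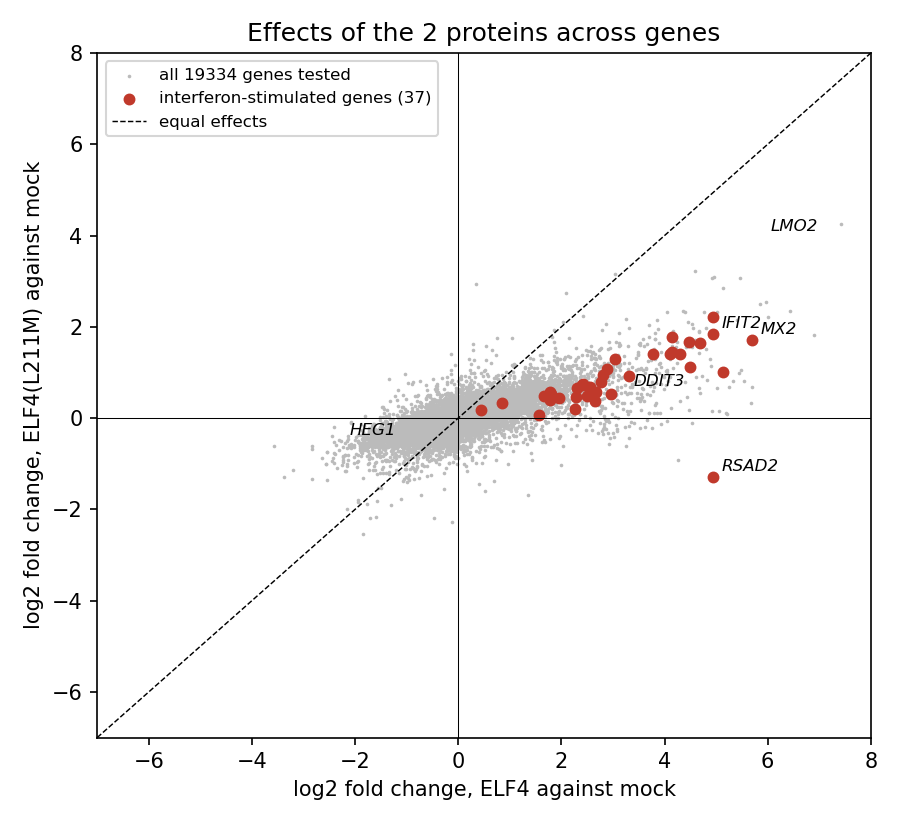
Log2 fold change against mock with ELF4 (horizontal) and with ELF4(L211M) (vertical) for all 19334 genes, with the 37 interferon-stimulated genes in red and the line of equal effects dashed. LMO2 lies at 7.42 and 4.24, and RSAD2 lies apart, with 1 of 3 mock arrays and 0 of 3 ELF4(L211M) arrays above background, so its vertical position is not a measured change.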

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

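The tests on shared mock arrays, mixing, virus amounts, slides and leukocytes were chosen after the result was seen, while those on the slide column and on other splits were written before.

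NTNG2 stood out because it was called in opposite directions with ELF4 and with ELF4(L211M). It was higher with ELF4 by 0.38 ± 0.10 (limma adjusted p = 0.0110) and lower with ELF4(L211M) by -0.43 ± 0.10 (adjusted p = 0.0443), a difference of -0.8108 (adjusted p = 0.000497) that follows from the choice of a gene with opposite calls and adds no independent support. The call against mock for the variant was lost within slide 2 (-0.38), and the difference was -0.22 and not called after normexp with quantile normalization.

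Of the 4430 genes called higher with ELF4, 798 were also called higher with ELF4(L211M). Chance differences between the mock arrays are argued against as the whole cause by a covariance of 0.21446, against a simulated 0.0238. The simulation held only the spread between arrays. A deviation common to all 3 mock arrays, as from a single culture, thus stays open. ELF4 cells or RNA mixed into the variant's samples would give each gene the same share of its ELF4 increase. The spread of that share between genes was 3.4766 times the median standard error of a gene's share between arrays. The share's 10th percentile was 1.94% and its 90th 41.9%. The limit of 3 for that ratio was set after the values of LMO2 and GIMAP6 were seen. The spread (14.5%) and both percentiles, over 1720 genes raised at least 2-fold with ELF4, also include the error between arrays (4.18%). That error is well below the spread, so the shares differed between genes by more than the arrays' error. For these genes as a set, this argues against mixing as the sole cause. A small mixed share beside another cause stays open, and the 10th percentile is no sure ceiling for it. A lower amount of the variant protein or virus cannot be told apart from a weaker protein, since the only ELF4 probe (0.26155) lies outside the coding sequence, and a weaker activity of the variant may be the reason, as a hypothesis.

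Interferon-stimulated genes were higher with ELF4 than with mock virus. A difference between slides is argued against by the design, since each slide held all 3 groups in the same proportion. The list's median was at least 2.7077 within each slide. For the slide column, genes matched on signal had a median of -0.058196 (724 genes), against -0.052 for all genes. Genes of the same brightness thus did not shift as a set, which the scaling of each array to its 75th percentile favours. Each group had its own column, so an effect of the column cannot be told apart from that of the virus. Different amounts of virus stay open, since the ELF4 probe (-0.35374) does not read the insert. An effect of the ELF4 protein may explain the rise, which was not tested apart from the virus dose or the slide column.

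Of 17 leukocyte markers 9 were called higher with ELF4. The list's call by camera was lost with an estimated correlation (adjusted p = 0.265) and with a trended, robust variance (adjusted p = 0.0535). Leukocytes or their RNA in these samples are argued against by a median of 0.033574 for PTPRC, TYROBP and FCER1G, with CD74 and HLA-DRA above background on 0 of 9 arrays, although PTPRC alone (0.29) was called with the array number (adjusted p = 0.00801) or the slide (adjusted p = 0.0238) as a block. Of the 17 measured markers 14 were above background on all mock arrays, which could hide a small share, and 0 were in another list. The cells had been sorted for EGFP, and induction of these genes within the carcinoma cells may be the reason, as a hypothesis.

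With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of these, 1 called as many genes as the real one, itself, in each comparison. The real counts were 9356, 1061 and 6997, and the highest of the other splits 0, 1 and 0. Each of the other splits put arrays of both real groups on either side. A real difference between the groups then adds to the spread within a side and lowers the count. Some of these splits also exchange arrays between numbers or slides. Their low counts therefore add no independent support.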

How the results depend on the processing

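The slide alternatives for gene lists and for the similarity of effects, and different mock arrays for the latter, were chosen after seeing the data. Where a value moved, the cause was not tested.

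The count for ELF4 against mock stayed within 1.5 times under all alternatives run, and so did that for ELF4(L211M) against ELF4. Counts past 2-fold fell with normexp, with quantile normalization or the 75th percentile, to 1491 and 1516 for ELF4, 64 and 61 for the variant, and 585 and 592 between them (903 with all 9 arrays above background). For the variant against mock, 173 genes (98 past 2-fold) were called without a filter, 290 (113) with only the 2 groups, 2747 with the array number as replicate block, 2372 with the slide as block, 196 (113) within slide 2, and 178 (40) by Student's test without moderation. Leaving out arrays gave 359 to 838 (121 to 203).

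The ELF4 probe kept -0.353742 without a filter and lost its call, with -0.409 to -0.310 over single arrays left out. Between the proteins it was called at 0.313 (quantile) and at 0.261553 (trended variance, replicate block, slide block), with 0.196 to 0.334 over arrays left out. Gene lists called with an estimated correlation were 0 in each comparison. Fry called 18 for ELF4, 5 for the variant and 15 between the proteins. Among these were 9 of the 9, 3 of the 6 and 10 of the 10 lists that camera called with the preset. The similarity was 0.795 (normexp and quantile), 0.545 (no filter), 0.799 (all arrays above background) 0.637 within slide 1 and 0.589 and 0.502 with different mock arrays, and 0.682 to 0.740 without single arrays.

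Other probes reversed IL1RN (0.103) and DST (0.333, and -0.173 between the proteins), and MX2 for the variant (-0.0715). VWF turned to -0.0791, -0.0455 and -0.173 for ELF4 (both normexp settings and its other probe), and to 0.0962, 0.0743 and 0.149 between the proteins.

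Of the named genes called, 104 of 119, 15 of 46 and 86 of 113 kept their call under all alternatives that were run on them. Student's test was not run on named genes. The filter for signal above background on all 9 arrays left 98, 36 and 92 of them, and those it removed were not counted as lost. The replicate block ended the call of TGM1 between the proteins (adjusted p = 0.0511) and added PTPRC (0.0285) and FCER1G (0.0346) there. Besides the calls given for PTPRC, CXCL8, CD68, IRF1 and PSMB8, and the counts and ELF4 probe above, it changed no other call. Signal over background limits the genes tested, since 49.8% to 64.2% of probes were well above background per array.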

Other observations

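The genes here were chosen after their values were seen, and no test here was planned for them.

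The RNA sensor gene TLR3 rose by 2.35 ± 0.13 with ELF4 (limma adjusted p = 4.8e-06) and by 0.98 with the variant (adjusted p = 0.0057). IRF3 rose by 1.26 and 0.93. IRF5 rose by 1.09 with ELF4 and by 1.16 with the variant, and the difference of 0.07 was not called (adjusted p = 0.57). IRF1 rose by 1.21 with ELF4, and its 0.43 with the variant was called with the array number as replicate block (adjusted p = 0.0241) or the slide as block (adjusted p = 0.0283) and not without a block. IFNL1 was at least 3.30-fold higher with ELF4.

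TAP1 rose by 1.01, PSMB8 by 1.11 and HLA-E by 1.15 with ELF4. With the variant HLA-E rose by 0.36 (adjusted p = 0.0322), and TAP1 had 0.21 (adjusted p = 0.255) and PSMB8 0.36 (adjusted p = 0.0668), called with the array number as replicate block (adjusted p = 0.0241) or the slide as block (adjusted p = 0.0210). GIMAP2 rose by 3.11 with ELF4 and by 1.12 with the variant. GIMAP6 was at least 12.4-fold higher with ELF4 and was not well above background on the mock or ELF4(L211M) arrays.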
